A study of Mus musculus with 4 samples.

How the data were processed

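RNA was extracted from gastric corpus, depleted of ribosomal RNA by an RNase H method, copied with random hexamers and sequenced as paired-end reads, per the labels' protocols. FastQC 0.10, Trimmomatic 0.33, Salmon 1.8.0 and edgeR are named, with the genome build given as both GRCm38 and mm10, per the submitters' processing notes. The role of each tool and the annotation release are not given in the sources used here.

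The values of the deposited table were not used. Its 4 columns of values are named by numbers that match no title, description or other label. A column was to be used only where its name matched a sample. The planned comparison of 2 misexpression with 2 control libraries, the gene list tests and all their alternatives were therefore not run. The columns of values were viewed only to learn their unit (the opening rows, ranges, totals and the share of values that were not whole), and no gene was compared between them. The results given here come from the columns that identify each gene. Of the 50961 rows, 50750 had an identifier in GENCODE M21, a GRCm38 annotation, which gave the coordinates of Sox9 and Fgf20.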

Results

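The series profiled RNA of the mouse gastric corpus, the acid- and pepsinogen-secreting part of the stomach, after forced expression of the transcription factor Sox9. The labels describe 4 samples: 2 from animals that were homozygous for a Cre allele of Fgf20 and carried a tetracycline-operator Sox9 transgene with the rtTA activator at ROSA26, and 2 from control animals with the transgene and the activator but without Cre. Doxycycline was given to both groups, controls included, for 2 weeks, starting at 8 weeks of age. How the Cre allele acts on the activator is not described here, and Sox9 induction was not measured in either group. The design addresses gene expression in this tissue under Sox9 misexpression, and its groups differ in the Fgf20 Cre alleles as well as in Sox9 misexpression.

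The deposited table has 50961 rows with 50960 distinct gene identifiers. Its rows comprise 21728 protein-coding genes, 9925 processed pseudogenes, 9762 lncRNA genes and smaller classes. Sox9 (ENSMUSG00000000567), which lies at chromosome 11, 112782224 to 112787760, on the plus strand of GRCm38, has a row. So does Fgf20 (ENSMUSG00000031603), at chromosome 8, 40279166 to 40308331, on the minus strand.

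The comparison of misexpression with control animals was not made. The table's 4 columns of values carry numbers that occur in 0 of the samples' labels, so no column was assigned to an animal or a group, and no level of Sox9 or of any other gene is reported. Column order was not taken as evidence of a group, and assigning columns by their Sox9 values would have presupposed the Sox9 difference itself.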

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

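No paired analysis was possible because the table's columns carry neither a sample's name nor a replicate number. The groups share replicate numbers, but nothing in the labels says that these mark a common litter or day. Because no column was matched to a sample, no test, scaling or filter of expression was run at all. The values of all 4 columns were left unused. In a check chosen after seeing the data, 50750 rows had an identifier in GENCODE M21 with the unplaced scaffolds included, the same number as on the reference chromosomes alone. That check bears on the gene identifiers and says nothing about expression.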
